A study of Mus musculus with 6 samples.

How the data were processed

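RNA was sequenced from 6 mouse large intestine samples, titled int 2 or int 3 with replicate numbers 1 to 3. Total RNA was taken up in TRIzol and made into libraries with a VAHTS Universal V10 kit, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments per kilobase of gene and per 1e6 fragments) with 35434 gene symbols and 6 columns, and the unit was taken from the table's name and its values. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the annotation and the handling of reads shared between genes or strands were not given in the sources used here. Each column was tied to the sample whose title it carries. The reference genome at hand was of another build, so genes are given by the symbols of the table and without coordinates.

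FPKM values of a gene are whole multiples of what 1 fragment is worth, and these steps gave back the depth. Between libraries the ratios of low values gave the relative depth, and the requirement that gene lengths be whole numbers of bases gave the totals (96.0% of the shortest genes within 0.05 bases). Whole fragments were found for 12417 of the 12525 tested genes (99.1%, relative tolerance 1e-06) and not for 108. They were used for read sampling noise and for 1 alternative test, and never for the main test. On 1997 simulated genes at a mean FPKM of 1 or more, 96.6% were given whole fragments, 96.7% of these exactly the simulated ones, and the library total was recovered to 100%.

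Genes at FPKM 1 or more in at least 3 of the 6 libraries were tested. The difference int 3 minus int 2 was fitted to log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A log2 change is the difference of group means on this scale, which understates the change of genes at low FPKM. All adjusted p-values of genes come from this fit. In the text a gene rose or fell when it passed this threshold. FPKM values are means ± SD over the 3 libraries of a group.

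Before the data were examined, 49 gene lists of cell types and processes were fixed, and 42 had at least 5 tested members. Of 895 listed symbols 872 were in the table. Each list was compared with the other tested genes by limma's camera with its preset correlation of 0.01 between genes, two-sided and adjusted over the 42 lists. It was run again with a correlation estimated for each list, and limma's rotation test fry was an alternative. Members passing the gene test were counted with adjustment over all tested genes and with adjustment over the list alone. The genes named in the text were also chosen by a rule fixed before the data were examined. Part of the rule takes the 8 genes with the largest log2 change in each direction among those at adjusted p under 0.05 whose groups do not overlap. It leaves out predicted or unnamed genes and immunoglobulin and T cell receptor segments, and it would fill a short direction with genes of log2 change 0.58 or more. Another part takes, for each list past the set test, the 3 members with the smallest p in the direction of the list and the first passing member of the opposite direction. The last part names 16 genes whatever their values, from Foxp3 and Il10 to Muc2 and Epcam. Any other gene named below was chosen after its values were seen.

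The fit was tested on simulated data with 200 changed genes among 12525 in a comparison of int 3 with int 2, 3 libraries each, over 10 draws. With equal spread in both groups it recovered 62.6% of 1.5-fold, 84.6% of 2-fold, 97.6% of 4-fold and 98.6% of 8-fold changes, and 5.61% of its calls were false. With the spread set to that of each group, 19.4% of the calls were false, because int 2 varied far less than int 3 and the fit assumes 1 spread. In these draws a shifted list was called 10 of 10 times and an unshifted list 0 times. Genes were drawn independently, so this does not tell how often a list of correlated genes is called falsely. In the data the estimated correlation reached 0.967, for the B cell list.

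Alternatives fixed before the data were examined were other pseudocounts (0.1 and 0.01), no filter, a mean FPKM of 5 or more, TPM, median-of-ratios and quantile scaling, leaving out abundant gene classes, the replicate number as a block, library weights, a robust prior, a test against a 1.5-fold change, and leaving out each library. After the data were seen 3 more were added: int 2 averaged to 1 sample, the same without int 3-1, and limma voom on the whole fragments. Mixtures of libraries, dispersion tests and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The mixing fit returned 30.0% for a simulated share of 30%.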

Results

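The series asked what a transfer of regulatory T cells (Tregs) does to the inflamed large intestine. Mice with inflammatory bowel disease (IBD) received either control Tregs or Tregs treated with lenvatinib, a drug that inhibits several receptor tyrosine kinases, and RNA of their large intestine was sequenced. The labels divide the 6 libraries into int 2 and int 3, with 3 libraries each, and do not say which number stands for which transfer. All differences are therefore given as int 3 minus int 2, and no treatment is assigned to either. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries and not that between animals.

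The libraries were of even depth. The steps in the FPKM values gave totals of 34.3, 34.4 and 34.2 M fragments (M, 1e6) for int 2-1, int 2-2 and int 2-3. For int 3-1, int 3-2 and int 3-3 they were 34.1, 34.0 and 35.1 M. The 10 most abundant genes took 18.6% to 21.2% of the FPKM sum, and mitochondrial genes took 15.1% to 18.3%. Xist was expressed in all 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were listed at 0 in all of them.

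Int 2 and int 3 differed in how far their libraries lay apart. Between any 2 int 2 libraries the log2 difference over the tested genes had an SD of 0.110 to 0.115. It was 0.302, 0.271 and 0.513 for the pairs int 3-1 and int 3-2, int 3-1 and int 3-3, and int 3-2 and int 3-3. The int 2 libraries still differed by more than independent sampling of fragments, with a mean chi-square per degree of freedom of 2.78 where such sampling gives 1. That does not show separate samples, and they are treated as 3 libraries only because the labels number them so. In int 3 that mean was 71.3. Hoxb13, a homeobox gene of the distal large intestine, stood at 287 ± 1.6 FPKM in int 2 and at 146, 16.4 and 267 in int 3-1, int 3-2 and int 3-3. Of 571 genes over 2-fold apart between int 3-2 and int 3-3, 99.3% had int 3-1 between them.

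**Figure D1:**
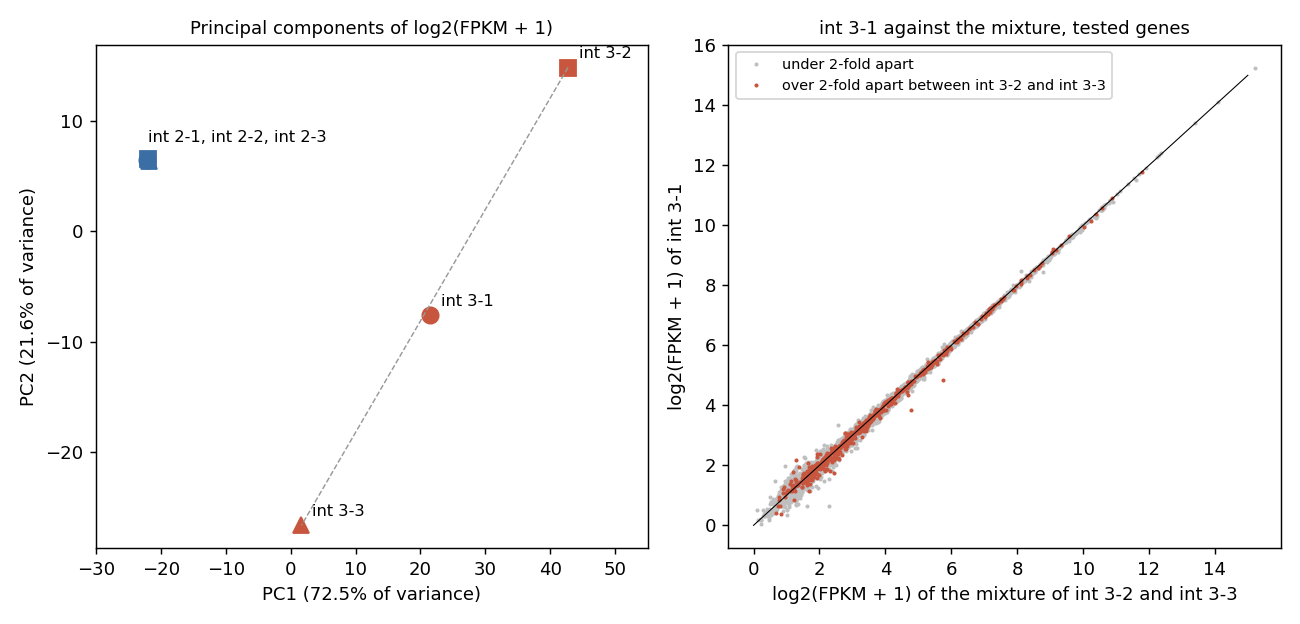
Left, principal components of log2(FPKM + 1) over the tested genes, with blue points for int 2 and red points for int 3, and symbols for replicates 1 (circle), 2 (square) and 3 (triangle). PC1 held 72.5% and PC2 21.6% of the variance, the 3 int 2 libraries fall on nearly the same point, and int 3-1 lies close to the dashed line between int 3-2 and int 3-3. Right, log2(FPKM + 1) of each tested gene in int 3-1 against a mixture of 48% int 3-2 and 52% int 3-3, with genes over 2-fold apart between those libraries in red and the line of equality in black.

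In int 3 the tissue carried more interferon-induced and inflammatory transcripts, more epithelial defence transcripts and fewer B cell and plasma cell transcripts than in int 2. The gene lists behind this statement passed the set test with its preset correlation, and none of them with an estimated correlation (smallest adjusted p = 0.081). Cxcl10, an interferon-induced chemokine, rose from 0.891 ± 0.0820 FPKM to 10.7 ± 1.01 (SD, n = 3 libraries each; log2 change 2.63, SE 0.08, adjusted p = 8.2e-05). Dmbt1, a secreted epithelial defence protein, rose from 164 ± 1.47 to 825 ± 65.9 (2.32, SE 0.07, adjusted p = 8.2e-05). Glycam1, a mucin-like glycoprotein made by the vessels through which lymphocytes enter lymphoid tissue, fell from 12.3 ± 1.53 to 0.260 ± 0.112 (-3.40, SE 0.11, adjusted p = 8.2e-05). Jchain, the joining chain of secreted antibodies, fell from 274 ± 2.86 to 55.2 ± 27.4 (-2.43, SE 0.37, adjusted p = 0.0096).

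Of the 12525 genes tested 1921 changed in limma's test, with 1082 higher and 839 lower in int 3. At least 2-fold changes on the log2 scale were seen for 178 higher and 143 lower genes. All 1921 had int 3 values that did not overlap the int 2 values, which held for 40.4% of all tested genes. Chance would give 10% only if all libraries were independent and equally spread. Int 2 varied far less than int 3, and independence is not stated, so the 40.4% cannot be judged against that 10%. The share of changed genes that were higher turned with the scaling. It was 56.3% in the deposited FPKM, 67.7% of 1883 with TPM, 51.3% of 1941 with median-of-ratios scaling, 48.5% of 2189 after quantile normalization and 46.6% of 1935 with voom, which was added after the data were seen. The count treats the libraries of each group as 3 samples. If the int 2 libraries are 1 sample, the calls are not established. Nor are they if int 3-1 is a mixture of int 3-2 and int 3-3. Int 3 would then hold fewer than 3 independent samples, and its SDs and p-values would be too small. With int 2 averaged to 1 sample, a choice made after the data were seen, int 3 alone supplies the spread. Such a fit cannot judge how many calls would hold. Its median log2 change over the tested genes was 0.0327, against 0.0338 in the main fit. The count was 635, 615, 637 and 642 without int 2-1, int 2-2, int 2-3 and int 3-1 and 4913 without int 3-3. Only 112 genes passed a test against a 1.5-fold change.

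The largest rises were those of Saa3, an acute-phase apolipoprotein (6.10), Clca4b, a member of the chloride channel accessory family (5.72), Hp, haptoglobin (3.56), and Isx, an intestinal homeobox factor (3.48). Next came Ccl8, a chemokine for monocytes and T cells (3.47), Slpi, a secreted protease inhibitor (3.41), Plet1, an epithelial surface protein (3.38), and Mmp3, a matrix metalloproteinase (3.27). Mptx1, a mucosal pentraxin, showed the largest fall, from 5351 ± 138 to 183 ± 177 FPKM (-6.17, adjusted p = 0.038). After Glycam1 came the B cell genes Fcmr (-2.84), Cd79a (-2.79) and Cd79b (-2.70), the lysozyme gene Lyz1 (-2.58), Reg4, a secreted lectin of colonic secretory cells (-2.56), and the B cell surface gene Ms4a1 (-2.46). Several of these were uneven within int 3. Saa3 stood at 122, 247 and 22.6 FPKM in int 3-1, int 3-2 and int 3-3 against 0.330 ± 0.336 in int 2, and Hp at 17.7, 35.1 and 1.68 against 0.0361 ± 0.0124. Plet1 stood at 57.9, 119 and 9.73 against 3.06 ± 0.0352 and Mptx1 at 185, 5.06 and 360. Without int 2-1, int 2-2, int 2-3 or int 3-1 in turn, Hp, Plet1, Mptx1, Fcmr, Cd79a, Cd79b and Ms4a1 no longer passed, with adjusted p from 0.0556 for Fcmr to 0.162 for Hp. With voom Saa3, Hp and Plet1 did not pass (adjusted p = 0.206, 0.176 and 0.168). With pseudocounts of 0.1 and 0.01 Cd79a (0.0516 and 0.0532) and Ms4a1 (0.0755 and 0.0932) did not. Without a filter Hp, Plet1, Mptx1, Cd79a and Ms4a1 did not pass (0.0618 to 0.0953), nor did the first 4 of these with the replicate number as a block (0.0609 to 0.0671). Clca4b, Mptx1 and Lyz1 have close paralogs, and their values are uncertain where shared fragments were split.

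**Figure D2:**
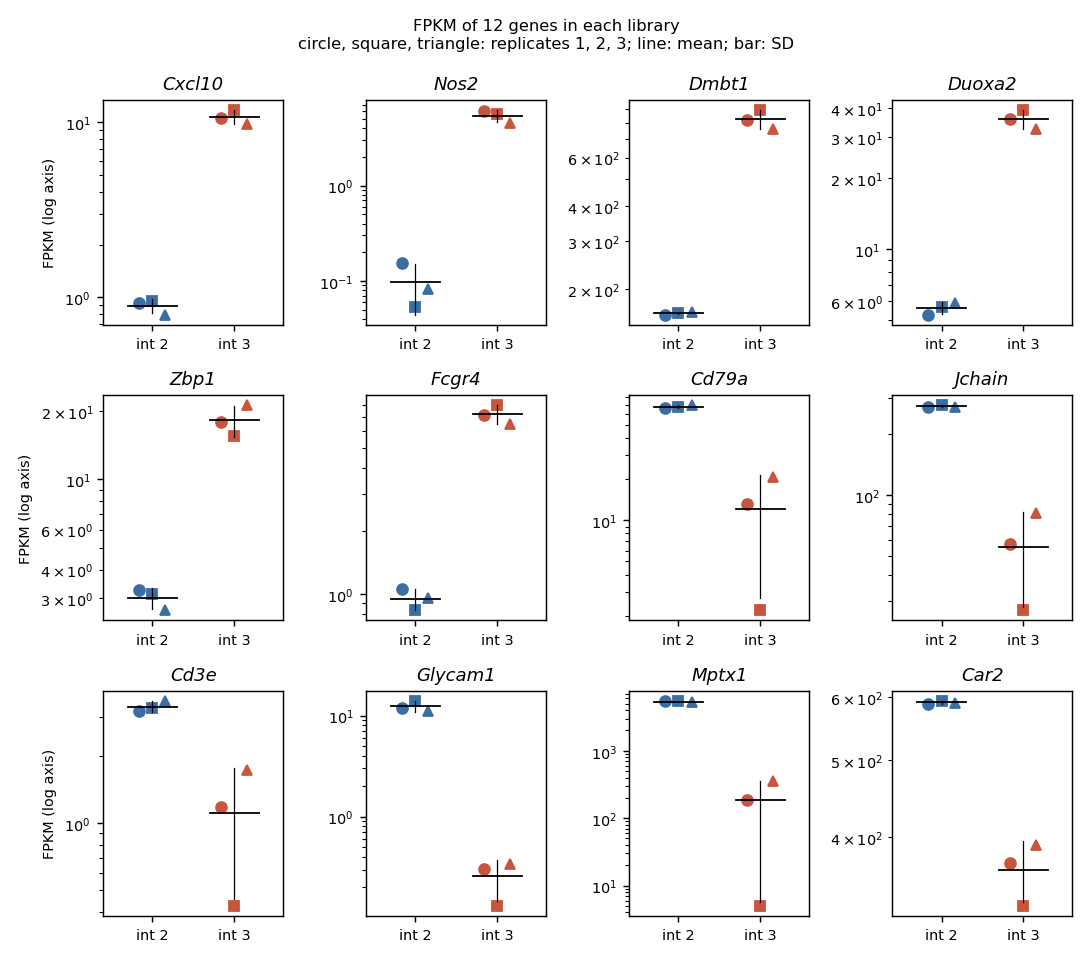
FPKM on log axes of 12 genes in each library of int 2 (blue) and int 3 (red), with replicates 1, 2 and 3 as circle, square and triangle, the group mean as a horizontal line and the SD as a vertical bar. Cxcl10, Nos2, Dmbt1, Duoxa2, Zbp1 and Fcgr4 were higher in all 3 int 3 libraries, and Cd79a, Jchain, Cd3e, Glycam1, Mptx1 and Car2 were lower, with a wide spread in int 3 for Cd79a (13.2, 2.20 and 20.8 FPKM in int 3-1, int 3-2 and int 3-3).

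Interferon-induced genes were higher in all 3 int 3 libraries. Of 18 tested members of the Th1 and interferon gamma list 15 rose and 3 did not pass (18 rose adjusted over the list alone), and the list lay above the other genes (camera adjusted p = 1.8e-14; adjusted p = 0.081 with an estimated correlation). Its median log2 change was 1.15, and the medians of int 3-1, int 3-2 and int 3-3 above the int 2 mean were 1.2, 1.03 and 1.17. Cxcl9, a chemokine for activated T cells, rose by 2.14 and Ido1, a tryptophan-degrading enzyme, by 2.28 (adjusted p = 9.8e-05 and 0.00015). Ifng itself stood at 0.0321 ± 0.0557 FPKM in int 2 and 0.128 ± 0.148 in int 3, below the filter. Among 23 tested type I interferon response genes 18 rose and 5 did not pass (23 rose adjusted over the list alone, and 8 to 22 rose with 1 library left out). The list had camera adjusted p = 3.1e-12, and adjusted p = 0.13 with an estimated correlation. Zbp1, a nucleic acid sensor, rose from 3.01 ± 0.316 to 18.2 ± 2.82 FPKM, Irf7, a transcription factor of the interferon response, from 9.75 ± 0.479 to 29.4 ± 4.74, and Rtp4 from 2.11 ± 0.111 to 6.79 ± 0.450 (adjusted p = 3e-04, 0.00097 and 0.00028). The medians of this list were 1.07, 1.34 and 0.78 in int 3-1, int 3-2 and int 3-3.

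Inflammatory cytokines and chemokines rose in 12 of 15 tested members, and 3 did not pass (12 rose adjusted over the list alone, and 7 to 13 rose with 1 library left out). The list stood above the other genes (camera adjusted p = 1.5e-07; adjusted p = 0.13 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 0.0973 ± 0.0528 to 5.42 ± 0.804 FPKM, and Cxcl5, a neutrophil chemokine, from 0.106 ± 0.0470 to 3.48 ± 0.380 (adjusted p = 0.00015 and 0.00016). The cytokine gene Il1b rose from 1.34 ± 0.267 to 4.70 ± 0.448 and Tnf from 0.394 ± 0.0715 to 1.92 ± 0.384 (adjusted p = 0.0013 and 0.0033). Il6 was below the filter at 0.0254 ± 0.0441 and 0.878 ± 0.306 FPKM, and Il17a at 0.0166 ± 0.0144 and 0.0251 ± 0.0250. Only 4 of the fixed neutrophil genes could be tested, too few for the set test. Of these 3 rose, S100a8 (0.0747 ± 0.129 to 6.70 ± 3.42 FPKM), S100a9 (0.0371 ± 0.0321 to 7.26 ± 5.23) and Cd177, and Ly6g did not pass (4 rose adjusted over the list alone, and 2 to 4 rose with 1 library left out). The adjusted p of S100a9, 0.015, was 0.0716 to 0.0757 without int 2-1, int 2-2, int 2-3 or int 3-1. S100a8 and S100a9 met the filter only because of their int 3 values, so the filter favoured rises among the tested neutrophil genes.

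Among 22 tested genes of monocytes and macrophages 13 rose, 2 fell and 7 did not pass (15 rose and 2 fell adjusted over the list alone). The set test gave camera adjusted p = 6.5e-06, and adjusted p = 0.13 with an estimated correlation. The Fc receptors Fcgr4 and Fcgr3 rose by 2.08 and 1.02, and C1qa, a complement component of tissue macrophages, from 33.6 ± 0.116 to 56.8 ± 3.15 FPKM (adjusted p = 0.00015, 0.00035 and 0.00089). Ly6c2, a marker of blood monocytes, fell from 10.7 ± 1.82 to 4.75 ± 0.625 FPKM (adjusted p = 0.0065). Of 8 tested type 2 response genes 5 rose, 1 fell and 2 did not pass (5 rose and 1 fell adjusted over the list alone, and 3 to 6 rose with 1 library left out). The list passed at camera adjusted p = 0.0098, and had adjusted p = 0.51 with an estimated correlation. The members that rose were Ccl8, the chitinase-like macrophage gene Chil3 (1.38), the receptor genes Il13ra1 (0.43), Il4ra and Il1rl1. Retnla, a resistin-like gene of alternatively activated macrophages, fell by 1.69 (adjusted p = 0.0062). Il4, Il5 and Il13 were below the filter. The type 2 call was lost at a mean FPKM of 5 or more (camera adjusted p = 0.12), and without a filter the list median was -0.04 (camera adjusted p = 0.93).

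B cell genes were lower throughout. All 14 tested members fell (14 adjusted over the list alone). Their median was -1.98, with camera adjusted p = 6.4e-11 and adjusted p = 0.29 with an estimated correlation. Fcer2a, the low-affinity IgE receptor of B cells, fell from 6.07 ± 0.362 to 0.606 ± 0.360 FPKM, Cd22 from 6.76 ± 0.206 to 1.04 ± 0.631 and Spib, a transcription factor, from 10.2 ± 0.229 to 3.03 ± 0.793 (adjusted p = 0.00097, 0.0036 and 0.002). The medians were -1.88, -2.48 and -1.39 in int 3-1, int 3-2 and int 3-3. Only 4, 4, 4 and 5 members fell without int 2-1, int 2-2, int 2-3 and int 3-1. Of 14 tested genes of lymphoid follicles 10 fell and 4 did not pass (11 fell and 2 rose adjusted over the list alone, and 5 to 10 fell with 1 library left out). The list had camera adjusted p = 1.2e-06, and adjusted p = 0.13 with an estimated correlation. Besides Fcer2a, Ccl21a, a chemokine that draws T cells and dendritic cells to lymphoid tissue, fell by 1.19 (adjusted p = 0.0014). Among 9 tested plasma cell genes 6 fell and 3 did not pass (6 adjusted over the list alone, and 2 to 6 fell with 1 library left out). Camera placed the list lower at adjusted p = 0.0018, and gave adjusted p = 0.13 with an estimated correlation. Tnfrsf13b and Irf4 fell by 1.19 and 0.99. Jchain had adjusted p of 0.0515 to 0.0527 without int 2-1, int 2-2 or int 2-3. The plasma cell call was lost at a mean FPKM of 5 or more (camera adjusted p = 0.12).

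T cell genes fell in 6 of 10 tested members, and 4 did not pass (7 fell adjusted over the list alone), with camera adjusted p = 1e-05 and adjusted p = 0.16 with an estimated correlation. Cd2 fell from 7.01 ± 0.116 to 1.63 ± 0.680 FPKM, Lck, a kinase of the T cell receptor, from 4.60 ± 0.209 to 2.32 ± 0.224 and Il7r from 2.05 ± 0.196 to 0.729 ± 0.165 (adjusted p = 0.0041, 0.0024 and 0.0043). Cd3e fell from 3.34 ± 0.185 to 1.11 ± 0.654 FPKM (adjusted p = 0.026, and 0.0904 to 0.109 without int 2-1, int 2-2, int 2-3 or int 3-1). Its adjusted p was also over 0.05 with pseudocounts of 0.1 and 0.01 (0.0513 and 0.0573) and without a filter (0.0608). Transcripts of the transferred cell type were scarce. Foxp3, the transcription factor that defines Tregs, stood at 0.227 ± 0.0557 FPKM in int 2 and 0.313 ± 0.0621 in int 3, and Il10 at 0.0604 ± 0.0353 and 0.181 ± 0.0885. Ctla4 stood at 0.610 ± 0.102 and 0.708 ± 0.276, and Il2ra at 0.648 ± 0.0548 and 0.437 ± 0.0729. All of these were below the filter and not tested. Of the 4 tested members of the Treg list, Tnfrsf18, Ebi3, Lrrc32 and Tgfb1, 0 passed (1 fell adjusted over the list alone, and 0 to 1 rose and 0 to 1 fell with 1 library left out). The list was too short for the set test.

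Genes of MHC class II presentation fell in 5 of 14 tested members, and 9 did not pass (5 adjusted over the list alone, and 0 to 12 fell with 1 library left out). Camera gave adjusted p = 4.8e-05, adjusted p = 0.51 with an estimated correlation, and fry gave adjusted p = 0.11. The members that fell were Ciita, the transactivator of these genes, and H2-Ob, H2-Eb2, H2-Oa and H2-DMb2, of which H2-Oa and H2-Ob encode the H2-O complex found mostly in B cells. Without int 2-1, int 2-2, int 2-3 or int 3-1, Ciita, H2-Ob and H2-Eb2 had adjusted p of 0.0688 to 0.0846. With a pseudocount of 0.01 H2-Eb2 and H2-Ob did not pass (0.0922 and 0.0509), and with one of 0.1 H2-Eb2 did not (0.0617). The list medians were -0.62, -1.76 and -0.05 in int 3-1, int 3-2 and int 3-3. Dendritic cell genes (8 tested, 1 rose, 2 fell, 1 and 2 adjusted over the list alone) and genes of the Th17 and IL-22 axis (8 tested, 1 rose, 3 fell, 1 and 4 adjusted over the list alone) did not pass the set test (camera adjusted p = 0.33 and 0.15). With 1 library left out, 1 to 2 of the dendritic cell genes rose and 1 to 3 fell, and 0 to 1 of the Th17 and IL-22 genes rose and 0 to 4 fell. Of 5 tested genes of cytotoxic and NK cells 0 passed (0 adjusted over the list alone, and 1 rose without int 3-2), and the list had a median of -0.00 and a mean of 0.11 (camera adjusted p = 0.89 for a shift up). Of 2 tested mast cell genes 0 passed (0 adjusted over the list alone).

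Epithelial defence genes rose in 14 of 23 tested members of the antimicrobial and epithelial alarm list, 3 fell and 6 did not pass (17 rose and 4 fell adjusted over the list alone). The list stood higher at camera adjusted p = 5.9e-06, and had adjusted p = 0.081 with an estimated correlation. Duoxa2, the maturation factor of an epithelial hydrogen peroxide source, rose from 5.61 ± 0.325 to 35.8 ± 3.37 FPKM (adjusted p = 8.2e-05). Lcn2, an iron-sequestering protein, rose from 2.31 ± 0.436 to 12.2 ± 7.24 (adjusted p = 0.037, and 0.116 to 0.141 without int 2-1, int 2-2, int 2-3 or int 3-1). Lcn2 was also lost without a filter (0.0793), with the replicate block (0.0712) and with voom (0.0827). Ly6d fell from 31.3 ± 1.34 to 11.4 ± 0.401 (adjusted p = 0.00015). Reg3g, an antimicrobial lectin, stood at 0.566 FPKM in int 2 and at 339, 737 and 0.775 in int 3-1, int 3-2 and int 3-3, and was not tested because only 2 libraries passed the filter. Reg3b was listed at 0 in all 3 int 2 libraries and at 1130, 2493 and 1.65 in int 3-1, int 3-2 and int 3-3. Unlike Reg3g it met the filter, but it did not pass the gene test.

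Absorptive colonocyte genes were lower, with 10 of 25 tested members falling, 1 rising and 14 not passing (12 fell and 2 rose adjusted over the list alone, and 4 to 16 fell with 1 library left out). Camera gave adjusted p = 1.5e-05, and adjusted p = 0.16 with an estimated correlation. Car2, a carbonic anhydrase, fell from 591 ± 2.47 to 363 ± 32.4 FPKM (adjusted p = 0.003). Abcb1a, a drug efflux pump, fell from 33.6 ± 0.731 to 14.9 ± 2.38 and Mep1a, a brush border protease, from 37.6 ± 1.03 to 26.2 ± 1.41 (adjusted p = 0.0022 and 0.0033). Slc51b, a bile acid transporter subunit, rose by 0.56 (adjusted p = 0.02, and 0.0869 to 0.0931 without int 2-1, int 2-2, int 2-3 or int 3-1). It was also lost with median-of-ratios scaling (0.0671) and the replicate block (0.0558). Tuft cell genes fell in 4 of 10 tested members and 6 did not pass (5 adjusted over the list alone, and 1 to 6 fell with 1 library left out). Camera placed this list lower at adjusted p = 0.00034, and gave adjusted p = 0.39 with an estimated correlation. Rgs13 fell from 2.74 ± 0.149 to 0.435 ± 0.295 FPKM (adjusted p = 0.0033). Of 7 tested small intestine genes 2 fell, Lyz1 and Anpep, and 5 did not pass (3 fell adjusted over the list alone, and 1 to 3 fell with 1 library left out). Its camera adjusted p of 0.047 became 0.51 with an estimated correlation, 0.35 without int 3-2 and 0.3 without a filter, where the median was 0.02. It was also over 0.05 under 8 further settings. Anpep was lost with the replicate block (adjusted p = 0.066).

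Goblet cell genes were uneven within int 3 and did not pass as a list (20 tested, 1 fell, 1 adjusted over the list alone, camera adjusted p = 0.67). Without int 3-3, 7 rose and 3 fell, and without int 3-2, 3 rose and 3 fell. Muc2, the main mucin of the colon, stood at 94.6 ± 1.35 FPKM in int 2 and 281 ± 182 in int 3 (log2 difference 1.31, adjusted p = 0.14). Its values were 274, 467 and 102 in int 3-1, int 3-2 and int 3-3. Retnlb, a secreted goblet cell protein, was at 49.3 ± 1.16 FPKM in int 2 and at 379, 771 and 54.9 in int 3. Epcam, a marker of all epithelium, stood at 689 ± 10 and 639 ± 44.7 FPKM (log2 difference -0.11, adjusted p = 0.31), and after quantile normalization the log2 difference was 0.02 with adjusted p = 0.76. Of 17 tested epithelium genes 1 rose (0 adjusted over the list alone, and 3 rose and 3 fell without int 3-3), with a median of 0.00, a mean of 0.04 and camera adjusted p = 0.77 for a shift down. Tight junction genes (17 tested, 0 passing, 0 adjusted over the list alone, and 3 rose and 2 fell without int 3-3) had a median of -0.01, a mean of 0.00 and camera adjusted p = 0.77 for a shift down. Enteroendocrine genes (15 tested, 1 rose, 2 fell, 2 and 3 adjusted over the list alone, camera adjusted p = 0.3) did not pass as a list, and 0 to 5 rose and 1 to 4 fell with 1 library left out. Nor did genes of stem cells and Wnt signalling (15 tested, 2 fell, 2 adjusted over the list alone, camera adjusted p = 0.077), of which 0 to 4 rose and 2 to 5 fell with 1 library left out. Of the distal Hox list 0 of 6 tested members passed (0 adjusted over the list alone, camera adjusted p = 0.98, and 0 to 2 rose with 1 library left out).

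**Figure D3:**
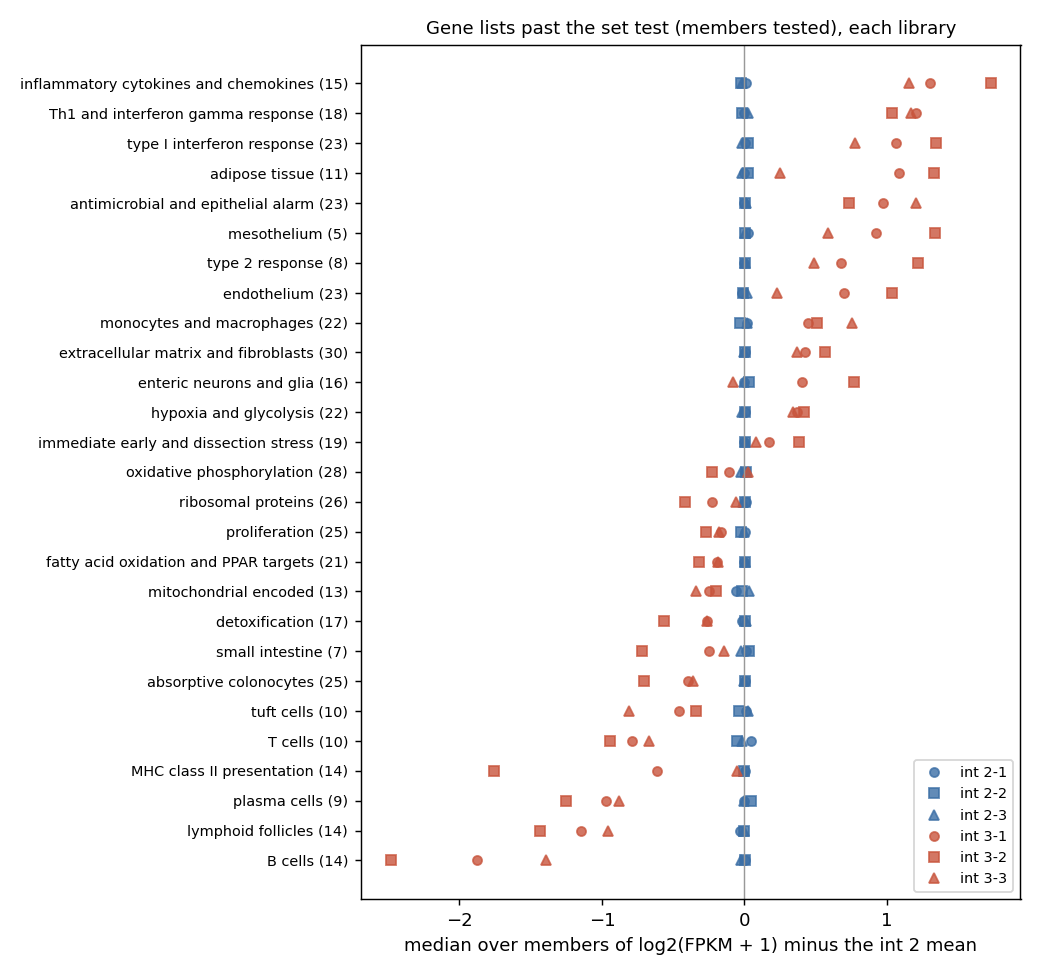
Median over the tested members of log2(FPKM + 1) minus the int 2 mean, in each library, for the 27 gene lists past the set test (members tested in parentheses), with int 2 in blue and int 3 in red and replicates 1, 2 and 3 as circle, square and triangle. The int 2 libraries sit near 0, and the int 3 libraries lie close together for the Th1 and interferon gamma list (1.2, 1.03 and 1.17) and apart for MHC class II presentation (-0.62, -1.76 and -0.05).

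Matrix and fibroblast genes rose in 17 of 30 tested members, 1 fell and 12 did not pass (19 rose and 1 fell adjusted over the list alone, and 11 to 23 rose with 1 library left out). The list stood higher at camera adjusted p = 9.2e-07, and had adjusted p = 0.16 with an estimated correlation. Timp1, an inhibitor of matrix proteases, rose from 1.5 ± 0.496 to 10.9 ± 3.16 FPKM and Col6a3, a collagen chain, from 7.22 ± 0.159 to 11.5 ± 0.421 (adjusted p = 0.0027 and 0.0015). Fap, a fibroblast protease, fell by 0.47 (adjusted p = 0.01, and 0.0582 to 0.0631 without int 2-1, int 2-3 or int 3-1, and 0.0544 with the replicate block). Endothelial genes rose in 5 of 23 tested members, 1 fell and 17 did not pass (19 rose and 2 fell adjusted over the list alone, and 0 to 18 rose with 1 library left out). Camera gave adjusted p = 0.00038, adjusted p = 0.51 with an estimated correlation, and fry gave adjusted p = 0.097. The endothelial medians were uneven, at 0.70, 1.03 and 0.23 in int 3-1, int 3-2 and int 3-3. Selp, the leukocyte adhesion molecule P-selectin, rose by 1.33 (adjusted p = 0.014, and 0.062 to 0.0716 without int 2-1, int 2-2, int 2-3 or int 3-1). Lyve1, a lymphatic endothelial marker, fell from 10.7 ± 0.0878 to 5.85 ± 0.411 FPKM (adjusted p = 0.0012). Of the 10 tested receptors that lenvatinib inhibits, Pdgfra rose, Fgfr3 fell and 8 did not pass (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.53). Without int 3-3, 5 of these receptors rose and 1 fell.

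Of 5 tested mesothelium genes 3 rose and 2 did not pass (3 adjusted over the list alone, and 1 to 4 rose with 1 library left out). The set test gave camera adjusted p = 0.01, adjusted p = 0.16 with an estimated correlation, and 0.074 without int 3-3. Upk3b, a mesothelial membrane protein, rose from 0.229 ± 0.0794 to 3.57 ± 0.261 FPKM (adjusted p = 0.00017). The members that rose, Upk3b, Msln and Upk1b, met the filter only because of their int 3 values, so the filter favoured rises in this list. Adipose genes rose in 3 of 11 tested members, 1 fell and 7 did not pass (7 rose and 1 fell adjusted over the list alone, and 1 to 9 rose with 1 library left out). This list passed at camera adjusted p = 0.026, and had adjusted p = 0.56 with an estimated correlation. Its medians were uneven, at 1.08, 1.33 and 0.25 in int 3-1, int 3-2 and int 3-3. Lpl, lipoprotein lipase, rose from 5.17 ± 0.330 to 12.3 ± 2.21 FPKM (adjusted p = 0.0039). Pck1, a gluconeogenic enzyme that colonocytes also express, fell from 68.3 ± 0.769 to 24.1 ± 1.81 (adjusted p = 0.00015). The adipose call was lost with TPM scaling (camera adjusted p = 0.086), at a mean FPKM of 5 or more (0.20) and with fry (0.34). Among 16 tested genes of enteric neurons and glia 2 rose, the glial gene Gfap (1.45) and Ednrb (1.26), and 14 did not pass (2 adjusted over the list alone, and 2 to 15 rose with 1 library left out). The list medians were 0.40, 0.77 and -0.08 in int 3-1, int 3-2 and int 3-3, so that int 3-3 lay on the other side of int 2. Camera gave adjusted p = 0.012, adjusted p = 0.56 with an estimated correlation, 0.057 without int 3-2 and 0.68 at a mean FPKM of 5 or more, and fry gave 0.097. Smooth muscle genes (17 tested, 1 rose, 3 fell, 2 and 4 adjusted over the list alone) did not pass camera (adjusted p = 0.071), though they passed fry (adjusted p = 0.00035). With 1 library left out 0 to 4 of them rose and 0 to 7 fell. Skeletal muscle genes did not pass camera either (5 tested, 1 rose, 1 adjusted over the list alone, camera adjusted p = 0.69, and 0 to 1 fell with 1 library left out). In lists too short for the set test, 0 of 4 erythroid genes passed (0 adjusted over the list alone, and 2 rose without int 3-3) and 2 of 4 pancreatic acinar genes fell (1 rose and 2 fell adjusted over the list alone, and 0 to 1 rose and 0 to 2 fell with 1 library left out). Of 2 squamous genes Sprr1a rose and Krt17 fell (1 and 1 adjusted over the list alone), and Sprr1a did not pass without int 2-1, int 2-2, int 2-3 or int 3-1.

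Genes of hypoxia and glycolysis rose in 15 of 22 tested members, and 7 did not pass (16 rose adjusted over the list alone, and 6 to 20 rose with 1 library left out). The list had camera adjusted p = 1.4e-08, and adjusted p = 0.081 with an estimated correlation. Bnip3, a hypoxia-induced mitophagy receptor, rose from 12.1 ± 0.255 to 27.5 ± 1.01 FPKM (adjusted p = 0.00017). The glycolytic enzyme genes Eno1 and Hk2 rose by 0.53 and 0.39 (adjusted p = 0.0028 and 0.0033). Genes of fatty acid oxidation and PPAR targets fell in 6 of 21 tested members, 2 rose and 13 did not pass (11 fell and 2 rose adjusted over the list alone, and 1 to 11 fell with 1 library left out). Camera placed them lower at adjusted p = 0.0022, and gave adjusted p = 0.13 with an estimated correlation. Acaa2, a thiolase, fell from 97.0 ± 2.26 to 66.4 ± 2.82 FPKM, while Angptl4, a lipase inhibitor, rose from 1.46 ± 0.182 to 4.75 ± 0.575 (adjusted p = 0.002 and 0.0012). Detoxification genes fell in 6 of 17 tested members, 1 rose and 10 did not pass (6 and 1 adjusted over the list alone, and 0 to 8 fell with 1 library left out). The set test gave camera adjusted p = 0.0061, adjusted p = 0.13 with an estimated correlation, and 0.067 without a filter. Ugt2b34, a glucuronosyltransferase, fell by 0.64 (adjusted p = 0.016, and 0.0709 to 0.0822 without int 2-1, int 2-2, int 2-3 or int 3-1).

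Proliferation genes fell in 8 of 25 tested members, and 17 did not pass (11 fell adjusted over the list alone, and 1 to 12 fell with 1 library left out). The list had camera adjusted p = 3.3e-05, and adjusted p = 0.085 with an estimated correlation. Cdk1, the mitotic kinase, fell from 13.0 ± 0.374 to 9.14 ± 0.293 FPKM (adjusted p = 0.0036). Of 26 ribosomal protein genes 0 passed (0 adjusted over the list alone, and 0 to 22 fell with 1 library left out), and their median was -0.22. The list lay below the other genes (camera adjusted p = 1.5e-05; adjusted p = 0.56 with an estimated correlation), but not after quantile normalization (0.065). Fry, which tests a list against no change and not against other genes, gave 0.17. Of 13 mitochondrially encoded genes ND3 fell and 12 did not pass (5 fell adjusted over the list alone, and 0 to 5 fell with 1 library left out). This list passed at camera adjusted p = 2e-05, and had adjusted p = 0.32 with an estimated correlation, and 0.088 after quantile normalization. ND3 had adjusted p = 0.018, and 0.0602 to 0.0967 without int 2-1, int 2-2, int 2-3 or int 3-1, 0.0795 with TPM and 0.0791 with the replicate block. Nuclear genes of oxidative phosphorylation had a median of -0.10, with 1 of 28 falling (Ndufa1) and 1 rising (Cycs) (0 adjusted over the list alone, and 0 to 10 fell with 1 library left out). Its median in int 3-3 lay on the other side of int 2 (-0.11, -0.23 and 0.02 in int 3-1, int 3-2 and int 3-3). Camera gave adjusted p = 0.004, adjusted p = 0.61 with an estimated correlation and 0.19 without int 3-2, and fry gave 0.29. Ndufa1 and Cycs had adjusted p of 0.0935 to 0.135 without int 2-1, int 2-2, int 2-3 or int 3-1, and of 0.0994 and 0.0802 with the replicate block. Ndufa1 was also lost without a filter (0.0663) and with median-of-ratios scaling (0.0625). In the immediate early and dissection stress list 7 of 19 tested members rose, 1 fell and 11 did not pass. Adjusted over the list alone, 7 rose and 1 fell. The list had camera adjusted p = 0.015, adjusted p = 0.51 with an estimated correlation, and 0.082 with library weights. A difference in tissue handling between the groups was not tested. Junb rose from 101 ± 1.76 to 179 ± 2.49 FPKM (adjusted p = 0.00028). Genes of endoplasmic reticulum stress (18 tested, 1 fell, 0 adjusted over the list alone) and cholesterol synthesis (20 tested, 4 rose, 1 fell, 4 and 1 adjusted over the list alone) did not pass camera (adjusted p = 0.3 for each). For cholesterol synthesis fry gave adjusted p = 0.044. Without int 3-3, 12 of the stress genes rose and 1 fell. For cholesterol synthesis 1 to 6 rose and 0 to 1 fell with 1 library left out.

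In total 27 of the 42 lists passed the set test with its preset correlation, 13 of them upward, and with an estimated correlation none did (smallest adjusted p = 0.081). Lists with an estimated correlation under the preset 0.01 lost their call too. Among them were hypoxia and glycolysis (-0.00024), antimicrobial and epithelial alarm (-0.025) and plasma cells (-0.11). Correlation between members therefore does not account for every loss. Each call also treats the libraries as independent samples, which the labels do not state. Where a range of counts with 1 library left out is given, the low end came without an int 2 library or int 3-1, and the high end without int 3-2 or int 3-3. Against the direction of a list past the set test, up to 4 members passed with 1 library left out.

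**Figure D4:**
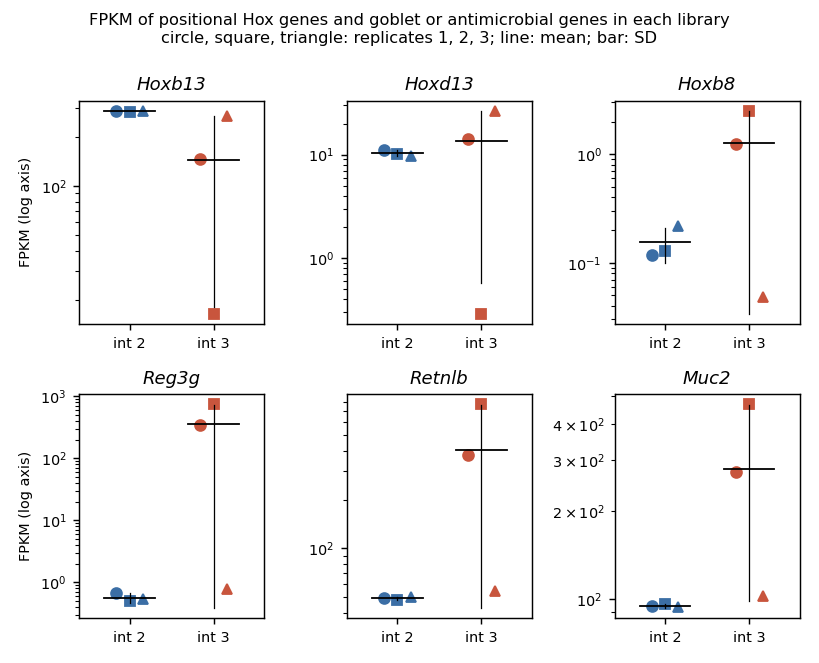
FPKM on log axes of 3 positional Hox genes and 3 goblet or antimicrobial genes in each library of int 2 (blue) and int 3 (red), with replicates 1, 2 and 3 as circle, square and triangle, the group mean as a horizontal line and the SD as a vertical bar. For all 6 genes int 3-2 and int 3-3 lie far apart and int 3-1 lies between them, as for Hoxb13 at 16.4, 267 and 146 FPKM. For Reg3g in int 3 the SD exceeds the mean, so the lower end of that bar was cut and does not mark the SD.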

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

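The alternatives that average int 2, that also leave out int 3-1, and that use voom were chosen after the data were seen. Against 1921 changed genes (1082 higher, 839 lower), the count was 9221 (5450 and 3771) with library weights, whose estimation stopped before it converged. It was 112 (72 and 40) in the test against a 1.5-fold change, which asks for more. With int 2 averaged to 1 sample, with or without int 3-1, int 3 alone supplies the spread, so these fits cannot judge how many calls would hold. At a mean FPKM of 5 or more, where fewer genes are tested, 496 genes were lower. Leaving out 1 library gave 615 (without int 2-2) to 4913 (without int 3-3) changed genes, 372 (without int 3-1) to 3124 (without int 3-3) higher, 241 (without int 2-2) to 1789 (without int 3-3) lower, and 25 (without int 3-2) to 29 (without int 3-3) lists. With an estimated correlation between genes 0 of 42 lists passed, against 27. With fry 23 passed, of which 20 were among those 27. The others were smooth muscle, circadian clock and cholesterol synthesis. The pseudocounts, scalings, the robust prior and voom kept all counts within 1.5 times. Under each setting with a gene test, 100% of the main calls it tested kept their direction. All 1921 called genes had groups that did not overlap. Leaving out or averaging libraries or changing the pseudocount therefore could not turn their direction. Of the named genes, 61 of 99 calls held with each of the 6 libraries left out, and of the lists 23 of 27. Most named genes were picked for a large change or a small p, so this share does not stand for all calls. If int 3-1 is a mixture of int 3-2 and int 3-3, fits without int 3-2 or int 3-3 keep part of the library left out. Of the 1921 calls, 615 (without int 2-2) to 641 (without int 3-1) were kept when an int 2 library or int 3-1 was left out.

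The median of the type 2 response list reversed without a filter (-0.0411, adjusted p = 0.93), and Epcam, which had not passed, reversed after quantile normalization (0.0219, adjusted p = 0.76); the cause was not tested, nor for the library weights. Limma with the replicate number as a block called 889 genes (516 higher, 373 lower). The numbers showed no sign of pairing the samples. Deviations from the group means of the same-numbered libraries correlated at -0.0147, 0.00407 and -0.0215 across genes. The highest correlation was 0.0445, between int 2-3 and int 3-1. The int 2 libraries differed so little that these values cannot exclude a pairing. Depth was even, at 34.0 to 35.1 M fragments per library, and its effect on the calls was not tested. It limits what can be said of genes under 1 FPKM, among them Foxp3 and Ifng, which were not tested.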

Other observations

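Tests chosen only after the result was seen are that of read sampling in int 2, that of the mixture in int 3-1 and both tests on intestinal segment; the splits of the libraries, the variable genes in int 2 and the graded levels in int 3-1 were set before their results were seen.

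Clock genes changed in opposite directions (14 tested, 4 rose, 3 fell and 7 did not pass, 5 and 3 adjusted over the list alone). Their list as a whole did not pass camera (adjusted p = 0.66), though it passed fry (adjusted p = 0.00088). The output gene Dbp rose from 1.65 ± 0.161 to 3.85 ± 0.387 FPKM, Tef from 2.62 ± 0.0234 to 4.41 ± 0.0408, and the repressors Nr1d1 from 8.48 ± 0.144 to 20.6 ± 6.20 and Nr1d2 from 6.29 ± 0.163 to 11.7 ± 0.643 (SD, n = 3; limma adjusted p = 0.0024, 0.002, 0.016 and 0.00097). Bmal1, the activator that Nr1d1 and Nr1d2 repress, fell from 3.04 ± 0.0876 to 1.48 ± 0.0708, and Npas2, which encodes a partner of its protein, from 5.67 ± 0.200 to 3.27 ± 0.853 (adjusted p = 0.0017 and 0.034). With 1 library left out 3 to 6 clock genes rose and 1 to 4 fell, the lower counts without int 2-1, int 2-2, int 2-3 or int 3-1. These genes were picked after their values were seen, and the labels give no time of collection.

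Levels of positional genes differed among the int 3 libraries. Hoxd13, of the distal gut, stood at 10.3 ± 0.675 FPKM in int 2 and at 14.2, 0.286 and 26.4 in int 3-1, int 3-2 and int 3-3, while Hoxb8 stood at 0.155 ± 0.0550 and at 1.24, 2.52 and 0.0483, and Hoxb6 at 1.46 ± 0.277 and at 4.11, 7.51 and 1.52. Tgm3, an epithelial transglutaminase, was at 296 ± 4.38 in int 2 and at 151, 2.05 and 274 in int 3, and Insl5, a hormone of colonic endocrine cells, at 231 ± 4.49 and at 85.7, 22.4 and 148. Cyp2c55 went the other way, at 51.6 ± 0.761 and at 42.8, 82.8 and 7.85. These genes were also chosen after their values were seen. Within the 1921 called genes, 354 had a smallest int 3 change of at least 0.8 of the largest, and 465 under 0.5.

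The 3 int 2 libraries differed far less than the int 3 libraries. A single library read 3 times, with each fragment counted once and independently, is argued against. The median int 2 dispersion was 2.43 times that of simulated read sampling (2.37 to 2.5, 95% interval over genes). The simulation drew fragments independently, and how they were counted is not known. Preparations from 1 RNA sample or pool would leave genes that vary between samples no more variable than others, and the 500 genes furthest apart between int 3-2 and int 3-3 had 1.08 times the int 2 dispersion of genes of like counts (0.885 to 1.2). That is consistent with 3 preparations of 1 RNA sample or pool, and animals that happened to be very alike stay open. Of the 10 splits of the libraries into 3 and 3, which are too few for a share under 0.05, 1, the real one, gave 1921 genes, and the highest of the others gave 0.

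Int 3-1 lay between int 3-2 and int 3-3. A linear mixture of 48% int 3-2 and 52% int 3-3 met its values with a log2 residual SD of 0.103. That was under the 0.110 to 0.115 between 2 int 2 libraries. The next best mixture for any int 3 library left 0.200, and no int 2 library was fitted as a mixture. Over the 571 genes more than 2-fold apart the share of int 3-2 had a median of 47.7% with quartiles of 43.1% and 52.3%, and medians of 41.7% to 49.3% in 8 gene lists. Levels graded on the log scale between int 3-2 and int 3-3 are argued against. A geometric mean left 2.21 times the residual SD of the linear mixture (1.70 to 2.82). An intermediate segment whose levels change linearly would meet the linear mixture equally well, so such a segment stays open. A candidate explanation is that int 3-1 holds RNA or reads of both other samples in nearly even shares. A separate animal made of both kinds of tissue, in the same shares for all genes, stays open. No biological explanation other than grading on the log scale was tested.

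Since Hoxb13 differed 16.3-fold among the int 3 libraries, the segment sampled could set some differences between int 3 and int 2. For the Th1 and interferon gamma list this is argued against as the whole cause, since the smallest int 3 library median was 0.860 of the largest; in the type I list it was 0.577. The 21 goblet and antimicrobial genes chosen for being over 2-fold apart within int 3 had a median ratio of the int 3-3 to the int 3-2 change of 0.0461. That median mixes genes that changed more in either library or in opposite directions, so it tells nothing about the cause, and a more proximal segment and a stronger inflammation in int 3-2 both stay open. The Treg transfer that the design names stays open as well, untested here because the labels do not tie it to a group.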
